A study of Mus musculus with 17 samples.

How the data were processed

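RNA from 17 mouse heart samples was profiled by sequencing: 5 control, 6 tumour and 6 tumour_swim. Per the labels, total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit from 1 µg of RNA. The submitters' processing notes name bcl2fastq, FastQC, fastp and the build mm10, without versions or roles; aligner, counting method, annotation, strandedness, sex, age and batch are not given in the sources used here.

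The deposited table, made by the authors, holds 28640 genes with 1 column per sample, and its values are FPKM, that is reads (or read pairs) per kilobase of exon and per 1e6 assigned reads. The unit is not named with the table and was inferred from the values: multiplied by the merged exon length of GENCODE M21, they sum to between 99.0% and 99.7% of the total expected for FPKM, and 98.6% to 99.0% of values below 20 reads fall within 0.1 of a whole number of reads. Column totals of 0.385 to 0.635 M exclude values scaled to a common total. Counts had been assumed when the analysis was laid out, so the written fallback for normalised values was used. Of the gene IDs, 28260 (98.7%) matched GENCODE M21 and 380 did not. Positions in the table equal those of GRCm38 for 621 IDs and differ for 27639, so positions were taken from GENCODE M21 by ID. Depth was recovered from the step between low values of FPKM times exon length, taken as 1 read. It ranged from 13.3 to 19.7 M reads, with a median of 15.8 M. The smallest chi-square per degree of freedom between libraries of a group was 11.5 over 40 pairs, well above the value near 1 that repeated sequencing of 1 pool would give, and the highest correlation between any libraries was 0.992. Xist did not exceed 0.0395 FPKM and Y-linked genes summed to at least 13.7 FPKM in every library.

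Gene tests used limma 3.58.1 in R 4.3.3 (limma-trend, two-sided) on log2(FPKM + 1) for the 13709 genes with a mean of at least 0.5 FPKM in at least 1 group. All 17 libraries entered a single fit with group as the only factor and 14 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg within each comparison at 0.05. Fold changes are on this scale, so they understate the change of genes near the floor, and the FPKM means are given beside them. The comparisons were tumour with control, tumour_swim with tumour and tumour_swim with control. The 37 gene lists (signalling, inflammation, cell type markers, heart muscle and metabolism), the tests and the alternatives marked as planned were fixed before the data were examined. Lists with at least 5 tested members, 34 in all, were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Estimating the correlation from the data left no list call in any comparison, with a smallest adjusted p of 0.130, 0.326 and 0.0506 in the order above. Fry, which asks whether the members of a list move on balance in 1 direction, called 8, 0 and 3 lists, and in either direction 18, 0 and 7; it does not compare a list with other genes. Counts adjusted over the list alone used the same p-values within each list.

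Genes were named by a rule: per comparison, the 10 with the greatest rise and the 10 with the greatest fall among genes past the threshold with a mean of at least 1 FPKM over the compared groups and a symbol other than a predicted gene, clone or locus number. Where none passed, the 5 with the smallest p were named. Each list added up to 2 members past the threshold, or the member with the smallest p, up to 10 opposed genes were allowed, and a fixed set with Akt1, Pik3ca, Bax, Bcl2, Il6, Tnf, Il1b, Nppa, Nppb, Fbxo32 and Trim63 was always included where tested. Of the 122 genes this picked, those that bear on the comparisons are printed; some of them are not reported here.

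Values of single libraries (6 measures in 3 comparisons) were compared by two-sided exact permutation tests in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The opposition of the tumour and swimming changes was set beside 100 simulated draws of unchanged groups that shared a simulated tumour group. The draws were made by shuffling residuals over all 17 libraries. The gene and list tests were tested on simulated data made from these libraries, 5 rounds per comparison. Of simulated 4-fold changes 93.3%, 94.2% and 94.8% were recovered in the 3 comparisons, of 2-fold changes 50.4%, 57.3% and 53.4%, and of 1.5-fold changes 14.3%, 17.3% and 12.8%, with 2.78%, 3.44% and 5.14% of the calls false. These changes were planted only in genes above a minimum mean read number, and each gene was drawn independently. The rates therefore do not cover lowly expressed genes or shifts shared by many genes of a library. The alternatives covered scaling, expression limits, pseudocount, threshold, weighting, pairing by replicate number, list tests and leaving out each library. Alternatives added after the values were seen were a robust estimate of the spread, array weights, the first principal component of the residuals as a covariate, removal of a length trend per library, and leaving out control 1, control 4 and tumour_swim 1. Raw reads were not analysed here.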

Results

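Hearts of mice were profiled by RNA sequencing in 3 groups: 5 hearts from mice without a tumour (control), 6 from mice carrying a transplanted CT-26 tumour (tumour) and 6 from tumour-bearing mice given swimming exercise (tumour_swim). CT-26 is a mouse colon carcinoma line that is grown as a graft. The series asks whether swimming alters the heart's response to a growing tumour, and its title names inflammation, apoptosis and PI3K-AKT signalling. No tumour-free mice swam, so tumour and swimming were not crossed. The labels do not say that the samples are separate animals, so the p-values measure the spread between these samples, part of which may be technical. Sequencing depth was 15.9 ± 1.06 M reads in control (SD, n = 5), 17.7 ± 1.83 M in tumour (n = 6) and 15.3 ± 1.07 M in tumour_swim (n = 6), with extremes of 13.3 M in tumour_swim 1 and 19.7 M in tumour 4. The median was 15.8 M, so a transcript near the lower limit of expression used here rests on few reads.

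Control 1, control 4 and tumour_swim 1 stood apart from the other 14 libraries. Mitochondrially encoded transcripts took 46.3% of reads in tumour_swim 1 and 30.8% in control 4, against a median of 22.1% over all 17. Control 1 did not stand out on this measure, at 26.2%, since tumour 1 had 29.7% and tumour 2 had 27.0%. In these 3 libraries long transcripts were under-represented: the Spearman correlation between exon length and the deviation from the other libraries of the group, taken across genes, which are not independent replicates, was -0.52 in control 1, -0.57 in control 4 and -0.55 in tumour_swim 1. Control 2 and control 3 had the opposite trend, with correlations of 0.56 and 0.58. Genes at or above 0.5 FPKM numbered 10773 in tumour_swim 1, 11852 in control 4 and 12605 in control 1. The first principal component, with 61.1% of the variance, separated the 3 libraries, and they fall in the control and tumour_swim groups, not in tumour.

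**Figure D1:**
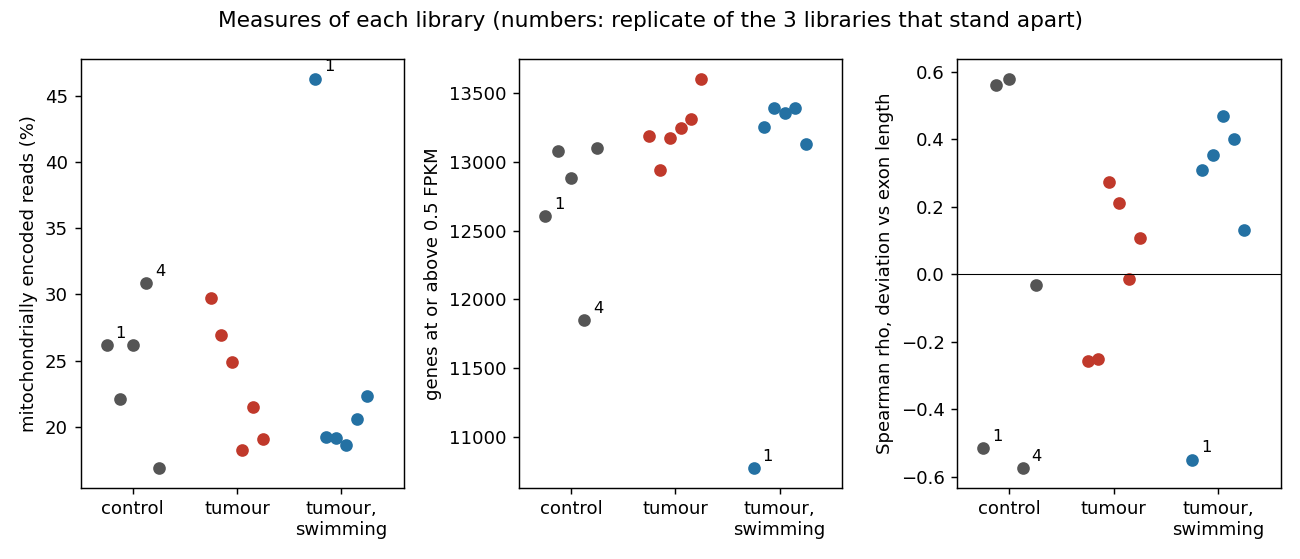
Share of reads from mitochondrially encoded transcripts (percent), number of genes at or above 0.5 FPKM, and Spearman correlation across genes of expression deviation with exon length, 1 point per library in the control (n = 5), tumour (n = 6) and tumour_swim (n = 6) groups. Tumour_swim 1 has the highest mitochondrial share, 46.3%, and the fewest genes, 10773.

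Tumour against control asks how the heart responds to a tumour growing elsewhere in the body. Hearts of tumour-bearing mice had higher levels of acute phase, inflammatory and neutrophil transcripts and lower levels of heat shock transcripts, of Acta1 and of the peptide hormone gene Apln. Serpina3n, a secreted serine protease inhibitor of the acute phase response (GRCm38 chromosome 12, + strand, 104406729 to 104414329), rose from 5.86 ± 1.79 FPKM in control (SD, n = 5) to 214 ± 98.3 FPKM in tumour (n = 6), a log2 fold change of 4.87 ± 0.37 (SE, limma adjusted p = 9.1e-07). Apln, which encodes apelin (chromosome X, - strand, 48025146 to 48034853), fell from 5.25 ± 1.76 to 0.418 ± 0.148 FPKM (log2 fold change -2.10 ± 0.16, adjusted p = 9.1e-07). Acta1, the skeletal actin that is co-expressed in heart muscle (chromosome 8, - strand, 123891769 to 123894751), fell from 2386 ± 572 to 340 ± 262 FPKM (log2 fold change -3.07 ± 0.48, adjusted p = 0.00104). All 6 tumour hearts lay above every control for Serpina3n and below every control for Apln and Acta1.

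Of 13709 genes tested, 704 were higher and 457 lower in tumour than in control hearts in limma's two-sided test at an adjusted p under 0.05. A change of 2-fold or more was seen in 218 of the higher and 74 of the lower genes. The groups did not overlap for 1427 genes, 830 of which passed, where chance gives 0.433% or 59.4 genes for 5 libraries against 6. The median log2 fold change of all genes was 0.14, which moved to -0.02 with median-of-ratios scaling and 0.00 with quantile scaling. The balance of the calls followed the scaling: median-of-ratios gave 944 higher and 964 lower, and quantile scaling 1072 and 1020. List values below are therefore given relative to the other genes.

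Among the genes with the greatest rises were further secreted and inflammatory products. Hp, which encodes haptoglobin, rose from 0.324 ± 0.171 to 16.1 ± 13.1 FPKM, and C3, the central complement component, from 19.8 ± 8.43 to 162 ± 58.6 FPKM. C4b, another complement component, rose by 3.28 on the log2 scale, Mmp3, a matrix metalloproteinase, by 3.04, the chemokine gene Cxcl14 by 3.03, and Srpx and Apod by 3.70 and 3.20. The non-coding imprinted transcript H19 had a log2 fold change of 2.87. Myc, a growth-promoting transcription factor, rose from 0.543 to 2.89 FPKM, and Igf1, a growth factor that acts through PI3K, from 1.47 to 4.91 FPKM. The further genes named here with their lists, beyond those picked by the rule, were chosen after their values were seen.

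The acute phase and IL6-STAT3 list rose together, with 13 of 20 tested members higher and none lower, and 17 higher when adjusted over the list alone. Its mean log2 fold change was 1.28 above that of other genes (camera adjusted p = 2.7e-12, and adjusted p = 0.130 with an estimated correlation). Besides Serpina3n and Hp, the risers included Lcn2, which binds bacterial iron carriers (2.16), Lbp, which binds bacterial lipopolysaccharide (1.80), and Socs3, a feedback inhibitor of STAT3 (1.51). In the list of inflammatory cytokines and NF-kB targets 11 of 31 members rose and none fell, 18 adjusted over the list alone, with a mean 0.58 above other genes (camera adjusted p = 2.2e-07, and 0.506 as an adjusted p with an estimated correlation). Il33, the alarmin cytokine, rose from 2.87 to 21.9 FPKM, Ccl11, the eosinophil chemokine, by 2.06 on the log2 scale, and the adhesion molecule genes Icam1 and Vcam1 by 1.17 and 0.82. Il1b had a log2 fold change of -0.07 (adjusted p = 0.868), and Il6 and Tnf lay below the expression limit, with group means up to 0.0563 and 0.385 FPKM. Without the 3 libraries that stood apart, the acute phase and inflammatory means were 1.36 and 0.60 above other genes.

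Markers of leukocytes rose in the same hearts. Of 9 tested neutrophil markers 7 were higher, 9 adjusted over the list alone, with a mean 1.17 above other genes (camera adjusted p = 5.9e-08). The adjusted p was 0.187 with an estimated correlation, and over the alternatives the mean lay between 0.54 and 3.20. Other members of the list lay below the expression limit, which a high tumour mean alone can meet. S100a8 and S100a9, which form the neutrophil protein calprotectin, had log2 fold changes of 2.37 and 2.64, with S100a8 going from 0.339 to 6.28 FPKM. Of 23 monocyte and macrophage markers 7 rose and none fell, 10 adjusted over the list alone, among them the scavenger receptor gene Cd163 (1.55), the mannose receptor gene Mrc1 (1.56) and Lyve1 (1.86). The list's mean was 0.49 above other genes (camera adjusted p = 0.000113, and adjusted p = 0.506 with an estimated correlation). Red cell transcripts were also higher: 4 of 11 erythroid markers rose, 5 adjusted over the list alone, including Alas2, the erythroid haem synthesis enzyme, from 8.07 to 31.4 FPKM. The erythroid list passed camera (0.60 above other genes, adjusted p = 0.0269, and adjusted p = 0.506 with an estimated correlation) but not with median-of-ratios scaling (adjusted p = 0.114), nor without control 3 (0.50), control 5 (0.57), tumour 5 (0.48) or tumour_swim 1 (0.60), where the adjusted p lay between 0.0529 and 0.0760. Haemoglobin transcripts took 0.299 ± 0.110% of reads in tumour and 0.134 ± 0.0414% in control hearts (exact two-sided permutation p = 0.00433, n = 6 and 5, and 0.0584 adjusted over 18 library comparisons). T and NK cell markers and lung markers had no member above the expression limit, and of 3 tested B cell markers Blk had a log2 fold change of -0.57, a call that was lost when any of 13 single libraries was left out (adjusted p = 0.0522 to 0.113).

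Chaperones fell in tumour hearts. Of 16 heat shock proteins 9 fell and none rose, 11 adjusted over the list alone, with a mean of -0.97 relative to other genes (camera adjusted p = 6.0e-10, and adjusted p = 0.194 with an estimated correlation). Hspb1, a small heat shock protein of muscle, went from 365 to 151 FPKM, and the co-chaperone genes Dnajb1 and Hsph1 had log2 fold changes of -1.55 and -1.42, Dnajb1 missing the threshold without tumour 3 (-1.50, adjusted p = 0.0516). Nuclear-encoded oxidative phosphorylation genes were lower as a group, with 10 of 74 members called and 30 adjusted over the list alone, and a mean of -0.79 relative to other genes (camera adjusted p = 1.4e-23, and adjusted p = 0.506 with an estimated correlation). Ndufs8 of complex I and Atp5g1 of the ATP synthase had log2 fold changes of -0.84 and -1.03. This group moved with the libraries that stood apart: without them its mean was -0.23 (camera adjusted p = 7.9e-06). Fatty acid oxidation and uptake genes had 5 of 38 members lower, 6 lower and 1 higher adjusted over the list alone, with a mean of -0.25 (camera adjusted p = 0.00052, and adjusted p = 0.599 with an estimated correlation), a call that quantile scaling ended at -0.03 (adjusted p = 0.612). Fabp3, the heart fatty acid binding protein, fell by 0.98 on the log2 scale.

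Contractile and stress genes went both ways. Of 20 cardiac stress and fetal genes 4 rose and 6 fell, and 4 and 7 adjusted over the list alone. Myh7, the slow myosin heavy chain that is fetal in the mouse ventricle, rose from 40.2 to 172 FPKM (adjusted p = 0.0088), and the metallothionein genes Mt1 and Mt2 by 1.46 and 1.65, while Csrp3 and Egln3 were among those that fell. This list's mean was -0.24 relative to other genes (camera adjusted p = 0.0315, and adjusted p = 0.506 with an estimated correlation), and it missed the threshold without control 2 (-0.23, adjusted p = 0.0607) or control 3 (-0.26, adjusted p = 0.0529). Among 24 sarcomere genes Myom2 rose by 1.42 and Actc1, Myl3, Tnnc1 and Tpm1 fell, Actc1 without passing under quantile normalization (-0.43, adjusted p = 0.30), and the list did not pass camera (adjusted p = 0.269). Acta2, the smooth muscle actin, fell from 197 to 38.5 FPKM, and smooth muscle and pericyte markers had a mean of -0.32 (camera adjusted p = 0.0368, and adjusted p = 0.776 with an estimated correlation), which missed the threshold with median-of-ratios scaling (adjusted p = 0.0681) and without control 2 (-0.28), control 3 (-0.30), control 5 (-0.26), tumour 5 (-0.28) or tumour_swim 1 (-0.32), at an adjusted p between 0.0529 and 0.0781. The actin genes share much of their sequence and the counting method is not stated, so reads may be shared between Acta1, Acta2 and Actc1, and likewise among the Serpina3 and globin paralogues. The natriuretic peptide genes Nppa and Nppb did not pass (log2 fold changes -0.05 and -0.70, adjusted p = 0.962 and 0.250), nor did the atrophy ubiquitin ligase genes Fbxo32 and Trim63 (0.84 and 0.15, adjusted p = 0.0572 and 0.614).

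Of the lists for the pathways that the title names, growth factors and apoptosis-promoting genes had called members in both directions, and the core and restraining lists had at most 1. In the PI3K-AKT core list 1 of 37 members, the leukocyte PI3K catalytic subunit gene Pik3cg, rose by 0.45 and none did so adjusted over the list alone. Pik3cg lost its call with the length trend removed (0.15, adjusted p = 0.491) and when any of control 1, control 4, control 5, tumour 2, tumour 3, tumour 4 and tumour 6 was left out (0.42 to 0.45, adjusted p = 0.0559 to 0.0801). The list's mean was 0.28 above other genes (camera adjusted p = 0.0157, and adjusted p = 0.914 with an estimated correlation), and without the 3 libraries that stood apart it was 0.09 (camera adjusted p = 0.170). Akt1 was at 42.0 and 47.9 FPKM in control and tumour hearts (log2 fold change 0.18, adjusted p = 0.522) and Pik3ca, a PI3K catalytic subunit gene, had 0.28 (adjusted p = 0.492). Among 35 growth factors and receptors that signal through PI3K, Osmr, Il4ra, Igf1 and Pdgfra rose and Vegfb and Angpt2 fell (9 and 2 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.102). Of 26 apoptosis-promoting genes Tnfrsf1a, Bmf, Fas, Casp12 and Bcl2l11 rose and Endog fell (7 and 4 adjusted over the list alone). Fas lost its call with median-of-ratios scaling (0.47, adjusted p = 0.136), and the list did not pass camera (-0.06 relative to other genes, adjusted p = 0.677, while its members' own mean was 0.06 and their median -0.02). It passed fry in either direction (adjusted p = 0.00028), a test that does not compare a list with other genes. Over all genes 8.47% were called. None of 18 apoptosis-restraining genes passed (adjusted p = 0.837), Bcl2 among them at 0.26.

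Stromal, hormone-responsive, clock and cell cycle lists also passed camera. Fibroblast markers had 6 of 16 members higher and Mfap5 lower, with a mean 0.45 above other genes (camera adjusted p = 0.0315, and adjusted p = 0.879 with an estimated correlation). Pdgfra, a receptor for platelet-derived growth factor, rose by 1.38, and the list missed the threshold without control 2 (0.48, adjusted p = 0.0544) or control 3 (0.41, adjusted p = 0.0777). Glucocorticoid-responsive genes had 7 of 21 members higher, such as the co-chaperone gene Fkbp5 (1.43), with a mean of 0.56 (camera adjusted p = 0.00044, and adjusted p = 0.506 with an estimated correlation). Circadian clock genes had no called member of 18 and a mean of 0.34 (camera adjusted p = 0.0442, and 0.884 as an adjusted p with an estimated correlation). Glycolysis genes had 1 of 26 members higher, the phosphofructokinase regulator gene Pfkfb3 (1.05), and 2 lower, with a mean of -0.17 (the same camera p-values). Neither list passed without the 3 libraries (adjusted p = 0.0773 and 0.0516). The circadian list also missed the threshold without control 1 (0.31), control 4 (0.24), control 5 (0.26), tumour 5 (0.31) or tumour 6 (0.31). The glycolysis list missed it without control 2 (-0.19), control 3 (-0.20), control 5 (-0.15), tumour 1 (-0.14), tumour 6 (-0.15) or tumour_swim 1 (-0.17), and quantile scaling turned its mean to 0.03. Cell cycle genes had Mcm4 higher and 4 lower, with a mean of -0.23 (camera adjusted p = 0.0168, and adjusted p = 0.776 with an estimated correlation), and missed the threshold without control 2 (-0.22, adjusted p = 0.0781) or control 5 (-0.18, adjusted p = 0.0807). The extracellular matrix list did not pass camera (adjusted p = 0.215), and 3 of its 34 members rose, among them the collagen cross-linking enzyme gene Lox (1.40) and the membrane metalloproteinase gene Mmp14 (1.48).

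Single libraries moved these counts. The higher genes numbered 333 without control 1, 315 without control 4, 360 without tumour 3, 371 without tumour 4, 386 without tumour 6 and 2642 without tumour_swim 1. The lower genes numbered 209 without control 1, 250 without control 4 or control 5, 291 without tumour 1, 212 without tumour 3, 251 without tumour 4 and 1024 without tumour_swim 1. Without the 3 libraries that stood apart 983 were higher and 748 lower.

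**Figure D2:**
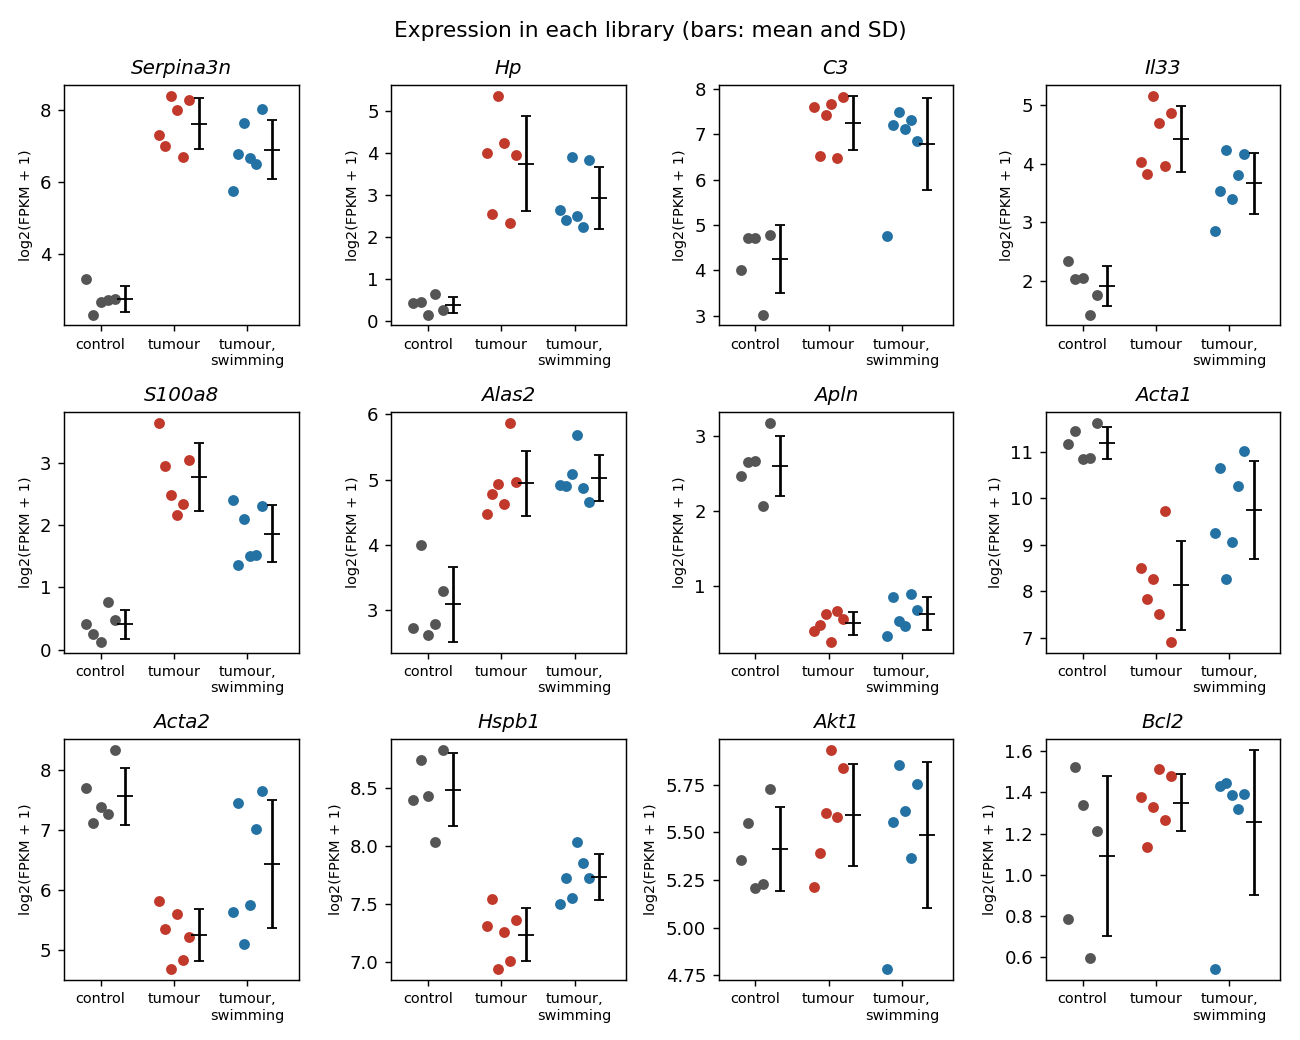
Expression of 12 genes in log2(FPKM + 1), 1 point per library, with bars for the group mean and SD in control (n = 5), tumour (n = 6) and tumour_swim (n = 6). Serpina3n lies above every control in the 6 tumour libraries, and the Akt1 means lie between 42.0 and 47.9 FPKM in the 3 groups.

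Swimming against no exercise in tumour-bearing mice asks whether exercise alters the heart's response. No single gene passed, and 9 of the 16 lists that had passed camera with the tumour passed in the opposite direction in hearts of swimming mice. The comparisons share the tumour libraries, which alone favours opposite directions, and the erythroid (0.11) and cell cycle (-0.01) lists did not lean back. Neutrophil, inflammatory, macrophage and acute phase genes stood lower relative to other genes than in tumour hearts, and heat shock and fatty acid oxidation genes stood higher, in camera with its preset correlation; none of these calls held with an estimated correlation. Acta1 had a mean of 1056 ± 690 FPKM in tumour_swim against 340 ± 262 in tumour (log2 fold change 1.63, limma adjusted p = 0.957, n = 6 and 6). S100a8 had 2.81 against 6.28 FPKM (log2 fold change -0.91), Il33 12.4 against 21.9 (-0.75), Hp 7.59 against 16.1 (-0.81) and Serpina3n 134 against 214 (-0.72), each with an adjusted p of 0.957.

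Limma called 0 genes higher and 0 lower, and 554 of 13709 genes (4.04%) had an unadjusted p under 0.05, where chance gives 5%. That number was 838 with median-of-ratios scaling, 1337 without the 3 libraries that stood apart and 2237 with array weights. Weighting changed this: limma's voom called 38 higher and 15 lower, and array weights 32 and 13. Without the 3 libraries that stood apart 1 gene passed, Ppp1r10, which encodes a regulatory subunit of a protein phosphatase (log2 fold change 0.74, adjusted p = 0.0358), and with no limit on expression 1600017P15Rik was lower. By rank of p the first were Hmgb2, a chromatin protein of dividing cells (3.55 and 1.74 FPKM in tumour and tumour_swim), Serpina3h, Zfp119b and the stress gene Gadd45b, with log2 fold changes from -0.80 to -0.57, and Tex49 with 0.82. None of these passed adjustment. The groups did not overlap for 51 genes, where chance gives 0.216% or 29.7 genes.

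The neutrophil list had the greatest shift, with 9 of 9 tested members lower in tumour_swim and a mean of -0.50 relative to other genes (camera adjusted p = 5.1e-08). The adjusted p was 0.326 with an estimated correlation, and 4 members passed adjusted over the list alone. A lowly expressed member can enter the test through its tumour mean alone, which favours lower values in tumour_swim. Over the alternatives the neutrophil mean lay between -0.99 and -0.24. Inflammatory genes had a mean of -0.18 (camera adjusted p = 0.000115), macrophage markers -0.22 (0.000175), acute phase genes -0.28 (0.00146) and glucocorticoid-responsive genes -0.17 (0.0277). With an estimated correlation the adjusted p was 0.728 for the glucocorticoid list and 0.537 for the others. Heat shock genes had a mean of 0.33 (camera adjusted p = 8.4e-06), fatty acid oxidation genes 0.14 (3.4e-05), cardiac stress genes 0.23 (0.00146) and oxidative phosphorylation genes 0.27 (5.7e-14), each with an adjusted p = 0.537 with an estimated correlation. The oxidative phosphorylation shift came with tumour_swim 1: without that library the mean was 0.02 (adjusted p = 0.390), and the cardiac stress list also missed the threshold without it (0.19, adjusted p = 0.0595). The glucocorticoid list missed it without tumour 1 (-0.15, adjusted p = 0.0983) or tumour_swim 1 (-0.09, adjusted p = 0.0676). No member of any list passed over all genes.

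None of the PI3K-AKT and apoptosis lists passed camera between swimming and non-swimming tumour hearts. The core list had a mean of -0.07 relative to other genes (adjusted p = 0.309) and the growth factor list -0.11, short of the threshold but past it with median-of-ratios scaling (adjusted p = 0.0404), with 0 of 37 and 0 of 35 members called, also adjusted over the list alone. Akt1 was at 45.1 FPKM in tumour_swim and 47.9 in tumour. Apoptosis-promoting genes had a mean of 0.00 (adjusted p = 0.621) and restraining genes -0.03 (adjusted p = 0.779). Leaving out tumour_swim 1 turned the direction of the core list, to 0.02, and it did not pass either way.

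The log2 fold changes of tumour against control and of tumour_swim against tumour had a correlation of -0.73 across genes, which are not independent replicates. Both comparisons share the tumour libraries, which alone gives a negative value: in 100 simulated draws without any effect the mean was -0.48, and 29 of 100 reached -0.73 or lower. The covariance was -0.0598, against a simulated mean of -0.0243, and 11 of 100 draws reached it or lower. The draws shuffled residuals over all 17 libraries, so the 3 that stood apart could fall in the simulated tumour group. The real tumour group holds none of them, so the draws do not give the value expected from sharing the real tumour libraries. With the tumour hearts split so that the comparisons shared no library, the correlation was -0.576 to -0.509 over 10 splits, and -0.428 to -0.358 without the 3 libraries that stood apart. No such split was drawn without an effect, so chance stays open. No gene passed in both comparisons with opposite signs. Without tumour_swim 1 the correlation was -0.36, and without those 3 libraries -0.60. The fold changes also followed exon length in opposite directions, with Spearman correlations across genes of 0.442 and -0.327, which were 0.117 and 0.0935 without those 3.

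**Figure D3:**
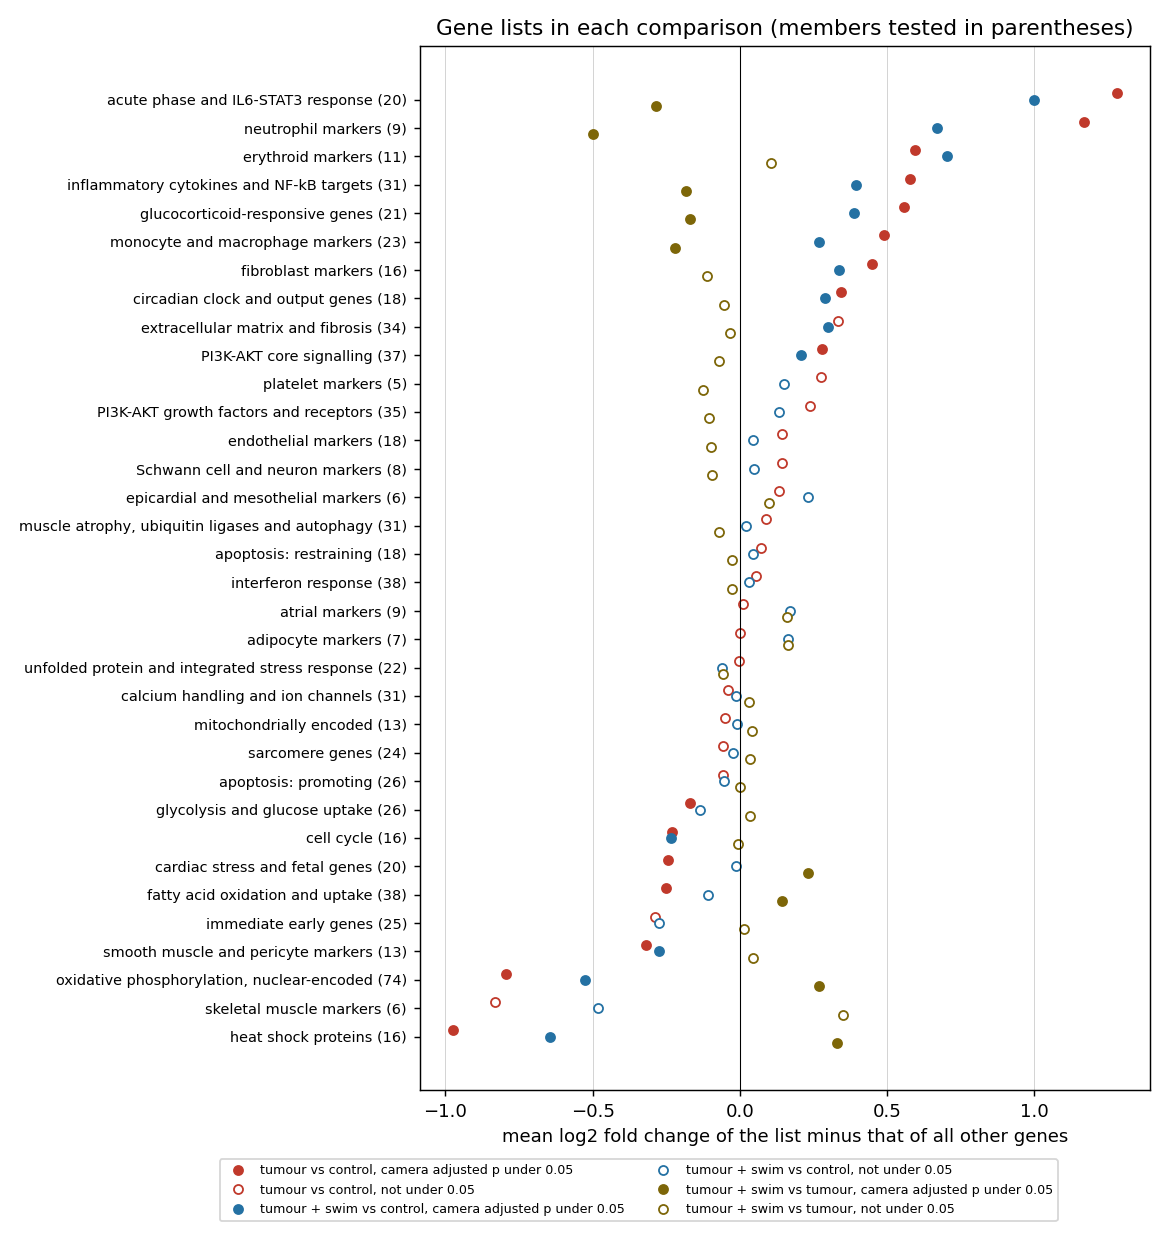
Mean log2 fold change of each of 34 gene lists minus that of the other genes tested, for tumour vs control, tumour_swim vs tumour and tumour_swim vs control, with filled points where camera's adjusted p with its preset correlation is under 0.05. The acute phase list lies at 1.28, -0.28 and 1.00 and the heat shock list at -0.97, 0.33 and -0.65 in that order.

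Tumour_swim against control asks what of the tumour response remains in swimming mice. Acute phase, inflammatory and erythroid genes were higher and Apln was lower in tumour_swim than in control hearts. Serpina3n was at 134 ± 77.3 FPKM against 5.86 ± 1.79 in control (log2 fold change 4.14, adjusted p = 1.1e-05, n = 6 and 5), Hp at 7.59 ± 4.77 against 0.324 ± 0.171 (2.54, adjusted p = 0.00777, and adjusted p = 0.123 with voom on recovered reads) and Apln at 0.561 ± 0.240 against 5.25 ± 1.76 (-1.97, adjusted p = 5.2e-06). All 6 tumour_swim hearts lay above every control for Serpina3n and below every control for Apln. Alas2 rose from 8.07 to 32.3 FPKM (adjusted p = 0.0014) and Mt1 from 126 to 365 (adjusted p = 0.0144), a call that was lost with median-of-ratios scaling (1.37, adjusted p = 0.099) and with only the 2 groups in the fit (adjusted p = 0.10).

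Of 13709 genes, 76 were higher and 48 lower in limma's test, 53 and 10 of them by 2-fold or more. The groups did not overlap for 217 genes, 94 of which passed, where chance gives 59.4 genes. All 76 higher and 46 of the 48 lower genes had also been called, in the same direction, in tumour against control. Independent lists give 3.90 and 1.60 shared genes, a figure that ignores the shared controls. Draws without any effect gave 0, which cannot judge the agreement, because such draws yield hardly any calls to share. The remaining 2 lower genes were Gm3235 and Gnb3 (log2 fold changes -0.81 and -0.83), named after their values were seen. Acta1 did not pass here (-1.44, adjusted p = 0.195). Whether the response was smaller than in tumour hearts is the comparison of tumour_swim with tumour, in which no gene passed. Of the 1161 genes called in tumour against control, 1157 had the same sign here, or 99.7%. Both comparisons share the control libraries: in 100 draws without any effect the same-sign share among as many genes of smallest p averaged 85.3%, and 6 draws reached the observed share. With the controls split into 2 and 3 so that none was shared, it was 50.5% to 97.4%, with 3 to 78 higher and 1 to 43 lower shared calls, so part of the agreement may come from the shared controls. The covariance of the log2 fold changes was 0.1245, against a simulated mean of 0.0261, and 2 of 100 draws reached it or higher. These draws also shuffled residuals over all 17 libraries, while the real controls include control 1 and control 4, which stood apart. They therefore do not give the agreement expected from sharing the real controls. With the controls split it was -0.0076 to 0.1235. The 4 exceptions in sign, Zfp119b, Pik3ip1, Gadd45b and Cth, had values between -0.10 and 0.00.

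Acute phase genes had 8 of 20 members higher, 14 adjusted over the list alone, with a mean 1.00 above other genes (camera adjusted p = 7.6e-16, and adjusted p = 0.0506 with an estimated correlation). Of 31 inflammatory genes Il33, Ccl11, Ccl6 and Cxcl14 rose, 11 adjusted over the list alone, with a mean of 0.39 (camera adjusted p = 1.4e-06, and adjusted p = 0.583 with an estimated correlation). S100a8 and S100a9 (adjusted p = 0.103 with voom on recovered reads) rose among 9 neutrophil markers (mean 0.67, camera adjusted p = 3.4e-06), and 3 of 11 erythroid markers rose with Alas2 (0.70, camera adjusted p = 2.8e-05), each with an adjusted p = 0.219 with an estimated correlation. Macrophage, glucocorticoid, fibroblast, circadian and extracellular matrix lists stood above other genes by 0.27, 0.39, 0.34, 0.29 and 0.30 (camera adjusted p = 0.00588, 0.00076, 0.0154, 0.0139 and 0.0310, and from 0.583 to 0.900 as adjusted p with an estimated correlation). Without 1 library the call was lost for macrophage markers (control 2, 0.22, or control 3, 0.21), fibroblast markers (control 3, 0.30), circadian genes (control 4, 0.19, or control 5, 0.21) and matrix genes (control 1, 0.20, control 4, 0.08, tumour_swim 2, 0.21, or tumour_swim 5, 0.25), and the matrix list stood at 0.05 without the 3 libraries that stood apart. Heat shock genes had a mean of -0.65 (camera adjusted p = 1.6e-08, and adjusted p = 0.219 with an estimated correlation), with Hspb1 lower at 213 against 365 FPKM, a call that was lost when any of control 1, control 2, control 5 and tumour_swim 2, 3, 5 and 6 was left out (adjusted p = 0.0508 to 0.103) and with quantile normalization (-0.55, adjusted p = 0.211). Oxidative phosphorylation genes had -0.52 and no called member (camera adjusted p = 6.6e-17), -0.21 without the 3 libraries, cell cycle genes -0.23 (camera adjusted p = 0.00021), and smooth muscle markers -0.28 (camera adjusted p = 0.0182, lost without control 2, -0.24, or tumour_swim 1, -0.13). With an estimated correlation their adjusted p was 0.583, 0.583 and 0.805. The called cell cycle members, Ccnb2 and Ube2c, were lower but both lost the call without control 1, control 5 or tumour_swim 3, 4, 5 or 6 (adjusted p = 0.0544 to 0.153), and Ube2c also without any of 9 other libraries.

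The PI3K-AKT core list had no called member of 37, also adjusted over the list alone. Its mean was 0.21 above other genes (camera adjusted p = 0.0127, and adjusted p = 0.860 with an estimated correlation). The list missed the threshold without control 4 (0.11, adjusted p = 0.0738) and with the length trend removed. Apoptosis-promoting and apoptosis-restraining genes stood at -0.06 and 0.04 (adjusted p = 0.489 and 0.837).

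Median-of-ratios scaling gave 184 higher and 186 lower genes and quantile scaling 202 and 171. The higher genes numbered 47 without control 1, control 5 or tumour_swim 4, 43 without control 4, 34 without tumour_swim 3, 42 without tumour_swim 6 and 1842 without tumour_swim 1. The lower genes numbered 21 without control 1 or tumour_swim 3, 29 without control 4, 18 without control 5, 28 without tumour_swim 2 or tumour_swim 4 and 366 without tumour_swim 1. Without all 3 libraries that stood apart 262 genes were higher and 90 lower.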

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

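The tests of sequencing depth, of tumour_swim 1 as a source of spread, of liver RNA and of the control libraries behind the acute phase rise were chosen after the results were seen.

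Control 1, control 4 and tumour_swim 1 stood apart from the other libraries in 2 of the 3 groups. Lower depth is argued against, because 2 of the 3 were deeper than the median library, at 17.4 and 16.6 M reads. For more cells of another type, 0 marker lists lay more than 1 log2 unit above the other libraries. This argues against it in control 1, where the highest list median was 0.21. It decides nothing for control 4 and tumour_swim 1, because the medians are not relative to other genes. Median-of-ratios size factors were 0.707 and 0.508 there, against 0.895 in control 1, so a typical gene also stood lower in them. A shortfall of long transcripts may account for the pattern. The correlation of expression deviation with exon length was at most -0.516 in each of the 3. Tumour 1 and tumour 2, which did not stand apart, had weaker negative correlations, -0.257 and -0.251. The size of these values depends in part on the reference, which is the other libraries of the same group. RNA of lower integrity would leave a shortfall of long transcripts, but no measure of integrity is given in the sources used here. A lower share of some non-muscle cells was not tested and stays open for control 4 and tumour_swim 1. Against the other libraries of the group, endothelial markers had medians there of -1.01 and -1.52. Fibroblast markers had -0.57 and -1.26, and smooth muscle markers -0.79 and -1.35. In control 1 these 3 lists were at -0.13, 0.01 and -0.04. In control 4 macrophage, neutrophil, erythroid and adipocyte markers lay within 0.04 of the other control libraries. None of these medians is relative to other genes, so they include the lower level of a typical gene in control 4 and tumour_swim 1.

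No gene passed between tumour_swim and tumour hearts. The spread that tumour_swim 1 adds does not account for this alone, since 0 genes passed without it, although array weights, which gave it a weight of 0.0583, called 32 higher and 13 lower genes. Of changes simulated at these group sizes, in better expressed genes only, 57.3% of 2-fold and 17.3% of 1.5-fold changes were recovered. The group sizes may therefore explain missing 1.5-fold changes. For 2-fold changes the recovery lies between the bounds set in advance and decides nothing. Chance could not be excluded for the 554 genes at an unadjusted p under 0.05, as 11 of 100 splits of the libraries gave as many, the highest other 1567. That swimming has a small effect or none stays open.

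Acute phase genes were higher in tumour hearts. Liver RNA is argued against, because the median log2 fold change of abundant liver transcripts was -0.0597 and albumin (Alb) stood at 0.725 FPKM in tumour hearts against 16.1 FPKM for Hp. The control libraries that stood apart are argued against as the whole cause, because 92.3% of the rising members, 12 of 13, still rose without the 3 libraries, the exception being Ch25h. Leukocytes in the tissue and a response of heart cells themselves were not separated, so a response to the tumour, which the design names, remains a hypothesis that may hold.

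Chance could be excluded for tumour against control, where 1 of 100 splits, the real one, gave 1161 genes and the highest other gave 11. For tumour_swim against control 4 of 100 splits, the real one included, gave at least 124 genes. That share met the bound set in advance, but it rests on few splits, so it does not exclude chance. The highest other split gave 5873 genes. That split put control 1, control 4, control 5, tumour_swim 1 and tumour_swim 2 on one side, which points to a structure of the samples other than the groups.

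Among 378 sets of values within a group, 37 held a library far from the others by Dixon's test, where chance gives 1 in 20, or 18.9, and 17 of the 37 were in tumour_swim 1. In tumour_swim 1 the mitochondrial share was 46.3% (18.7 to 22.3 in the other 5), the share of the 10 most abundant genes 45.4% (21.8 to 24.9), and the genes at or above 0.5 FPKM numbered 10773 (13133 to 13395). Its FPKM was higher than in the other 5 for mt-Co2 at 8595 (1405 to 2348), Mt2 at 20.9 (2.91 to 4.74), Bax at 14.3 (7.07 to 9.5) and Ndufb2 at 5.42 (2.64 to 3.38). The same library was lower for Bcl2 at 0.458 (1.5 to 1.73), Bhlhe40 at 2.36 (13.2 to 17.2), Birc2 at 2.93 (7.13 to 9.40), Birc3 at 0.629 (2.10 to 2.96) and Hmgb2 at 0.724 (1.77 to 2.28). It was also lower for Itgb3, listed at 0 (0.760 to 1.01), Mcm4 at 0.919 (3.05 to 3.96), Osmr at 1.03 (4.77 to 6.40), Pik3ca at 2.11 (6.94 to 8.66) and Scn7a at 1.52 (12.9 to 16.9).

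Tumour 5 had a haemoglobin share of 0.507% (0.186 to 0.303 in the other 5), Alas2 at 57.4 FPKM (21.1 to 30.3), Acta1 at 846 (119 to 359) and Fbxo32 at 29.3 (19.6 to 22.9). Control 5 had Acads at 133 FPKM (93.6 to 102 in the other 4), Actc1 at 3627 (2511 to 2728), Casp4 at 1.04 (0.577 to 0.655) and Nrep at 10.96 (7.11 to 7.83). Control 2 had Dnajb1 at 62.9 FPKM (7.67 to 18.5) and Il1b at 3.47 (0.253 to 0.722), control 1 Mstn at 0.828 (0.443 to 0.544) and control 4 S100a9 at 1.96 (0.64 to 0.892). Tumour 1 had Il1b at 1.47 FPKM (0.651 to 0.841) and Mt1 at 443 (285 to 338), and tumour 3 had Birc3 at 4.50 (2.76 to 3.33). Single values also stood out in tumour_swim 2 for Ccnb2 at 0.584 FPKM (0 to 0.198), tumour_swim 3 for Chek2 at 2.20 (0.799 to 1.25), tumour_swim 4 for Alas2 at 50.4 (24.2 to 33.0), tumour_swim 5 for Ntf3 at 1.17 (1.44 to 1.53) and tumour_swim 6 for Nppb at 586 (109 to 229).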

How the results depend on the processing

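Array weights, the residual component, robust spread, removal of the length trend and leaving out 3 libraries were chosen after the data were seen. Depth limits the lowly expressed genes most. In the simulation, which planted changes only in better expressed genes, 2-fold changes were recovered in about 50.4% to 57.3% of cases. Over all alternatives the named genes kept their side of the threshold in 6506 cases. They lost the call in 388 and gained it in 156, and none changed sign with a call on either side. Of the 202 gene results, 69 were called as reported in tumour against control, 35 in tumour_swim against control and 0 in tumour_swim against tumour. Genes and lists that stayed uncalled are among those kept, so the totals overstate how far the calls held. The lists on signalling, inflammation and apoptosis kept their side in 414 cases, lost a call in 17 and gained it in 1, and other lists kept it in 2960, lost a call in 170, gained it in 76 and changed sign with a call in 10. Sign changes without a call count as kept here, such as those of the core list between tumour_swim and tumour (-0.14 to 0.02) and of the apoptosis-promoting list between tumour and control (-0.10 to 0.06). Counts of called genes stayed within 1.5 times in 160 and moved in 85, and counts at an unadjusted p under 0.05 stayed in 86 and moved in 19. The called counts of tumour_swim against tumour and of opposed genes were 0 as reported. A count that stayed at 0 is among the 160, which therefore overstates how far the other counts held. The planned count-model Wald test, the quasi-likelihood fit without robust estimation and the fit with 1 surrogate variable were not run, because they model counts or need a tool for counts and the table holds FPKM. Reads recovered from it entered only limma voom, and the first principal component of the residuals took the place of the surrogate variable. Scaling by library size alone equals the values as deposited. The cause was not tested for any change below, except where the construction shows it.

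For tumour against control, the genes higher (704) became 1356 without mitochondrial genes in the scaling, 1158 with voom, 1072 with quantile scaling, 1315 at a threshold of 0.1, 218 with a minimum change of 2-fold, 1512 with only the 2 groups fitted, 1108 with array weights and 1217 with the length trend removed. The genes lower (457) became 964 with median-of-ratios scaling, 1020 with quantile scaling, 812 at 0.1, 74 at 2-fold, 1168 with the length trend removed, 748 without the 3 libraries that stood apart and 1166 with both that omission and median-of-ratios scaling. The first principal component of the residuals as a covariate gave 4984 and 1780, and it is orthogonal to the groups by construction, so these counts are overstated. Of the 1161 genes called, 937 were called with median-of-ratios, 1016 with voom, 985 with quantile scaling and 921 without the 3 libraries.

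For tumour_swim against tumour, voom gave 38 higher and 15 lower, array weights 32 and 13, the residual component 72 and 857, the omission of the 3 libraries 1 higher, and no expression limit 1 lower. The genes opposed between tumour and swimming (0) numbered 35 with voom, 1 with no expression limit, 30 with array weights, 889 with the residual component and 1 without the 3 libraries.

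For tumour_swim against control, the genes higher (76) became 184 with median-of-ratios, 153 without mitochondrial genes in the scaling, 477 with voom, 40 with no expression limit, 202 with quantile scaling, 123 at 0.1, 33 with only the 2 groups fitted, 409 with array weights, 2497 with the residual component, 286 with the length trend removed, 262 without the 3 libraries and 268 with both. In the same order, where they moved, the genes lower (48) became 186 with median-of-ratios, 102 without mitochondrial genes, 126 with voom, 171 with quantile scaling, 120 at 0.1, 10 at 2-fold, 12 with only the 2 groups, 106 with array weights, 1068 with the residual component, 224 with the length trend removed, 90 without the 3 libraries and 242 with both. Of the 124 genes called, 99, 104, 107 and 104 were called with median-of-ratios, voom, quantile scaling and without the 3 libraries.

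The shared replicate numbers do not appear to pair the samples. After removal of the group means, residuals of same-numbered libraries correlated from -0.358 to 0.355 between tumour and control. The range was -0.204 to 0.518 between tumour_swim and tumour and -0.670 to 0.677 between tumour_swim and control. In that order, 1 of 5, 2 of 6 and 1 of 5 libraries correlated best with their own number. Pairing is not excluded by these values. With a replicate block, tumour against control gave 263 and 179 genes, tumour_swim against tumour 0 and 0, and tumour_swim against control 21 and 4.

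The PI3K-AKT core list in tumour against control (0.28) lost its call with the length trend removed (0.12), without the 3 libraries (0.0948), with both omission and median-of-ratios (0.0916), with an estimated correlation (0.28, adjusted p = 0.914), and in fry in 1 direction (0.39) and in either (0.2783). In tumour_swim against control (0.21) it lost it with the length trend removed (0.10), an estimated correlation (0.2068) and fry (0.2512 and 0.2068). The inflammatory list lost its call with an estimated correlation in all 3 comparisons (0.5769, -0.182 and 0.3949), in fry for tumour_swim against tumour (-0.2531 and -0.182) and in directional fry for tumour_swim against control (0.439). The values for fry in 1 direction (0.39, 0.2512, -0.2531 and 0.439) are the members' own mean log2 fold changes. They are not relative to other genes, so they cannot be set beside the other values. The apoptosis-promoting list (-0.0576) passed fry in either direction. Glycolysis reversed in tumour against control with quantile scaling (0.0344). In tumour_swim against tumour the mitochondrially encoded list (0.0424) reversed with voom (-0.2855), array weights (-0.2684), without the 3 libraries (-0.2912), with median-of-ratios as well (-0.3046) and without tumour_swim 1 (-0.291; the highest with any other library left out was 0.144), and the extracellular matrix list (-0.0335) reversed with voom (0.1881), array weights (0.1719), without the 3 libraries (0.1493) and with median-of-ratios as well (0.1453).

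Leaving out each library in turn gave 315 to 2642 higher and 209 to 1024 lower genes for tumour against control, 0 for tumour_swim against tumour and for opposed genes, and 34 to 1842 higher and 18 to 366 lower for tumour_swim against control. Genes at an unadjusted p under 0.05 numbered 2563 to 5899, 370 to 757 and 1163 to 5677 in that order, and the correlation of the opposed changes lay between -0.766 and -0.361. The core list ranged over 0.1849 to 0.3624, -0.1096 to 0.0242 and 0.1134 to 0.3025, the inflammatory list over 0.5309 to 0.6301, -0.2352 to -0.1432 and 0.3489 to 0.4353, the apoptosis-promoting list over -0.1009 to -0.0205, -0.0324 to 0.0248 and -0.0992 to -0.0188, and the restraining list over 0.0441 to 0.0893, -0.0385 to -0.0094 and 0.0162 to 0.0612.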

Other observations

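The test of Acta1 against the acute phase score, the test of that score between tumour_swim and tumour, and the genes called with library weights were chosen after the results were seen.

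With library weights, single genes passed between tumour_swim and tumour hearts. Of 45 genes called with array weights and 53 with voom, 42 were the same, 31 of them higher and 11 lower in tumour_swim. The genes named here were picked from these after their values were seen and were not tested as a group, and the sarcomere list did not pass (0.03 relative to other genes, adjusted p = 0.223). The higher genes included the cardiac transcription factor genes Hand2, at 21.7 ± 4.88 FPKM in tumour and 39.6 ± 13.7 in tumour_swim (SD, n = 6 each, array-weighted log2 fold change 1.04, limma adjusted p = 0.0101), and Nkx2-5, at 33.6 and 48.0 FPKM (0.62, adjusted p = 0.0447), the muscle gene regulator Srf, at 22.9 and 31.4 FPKM, and the chaperone gene Hspb1 (0.57, adjusted p = 0.0339). The lower genes included S100a8 (-1.02, adjusted p = 0.0339), Hmgb2 (-0.63, adjusted p = 0.0135), Arrdc3, which restrains adrenergic receptor signalling, at 11.8 and 6.67 FPKM, and Nt5e, which makes adenosine, at 3.47 and 2.18 FPKM. None of these passed in the fit as reported, and S100a8, Hmgb2 and Hspb1 passed also with the first principal component of the residuals as a covariate, whose counts are overstated.

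Further gene groups did not pass camera between tumour and control hearts as reported, although atrial markers had 3 of 9 members called, Schwann cell and neuron markers 2 of 8 and skeletal muscle markers 2 of 6. Of 38 interferon response genes Iigp1 and Zbp1 were higher and Isg15 lower. Iigp1 lost its call without control 4 (0.92, adjusted p = 0.0608), and Zbp1 without any of control 1, control 4, control 5, tumour 3, tumour 4 and tumour 6 (0.35 to 0.45, adjusted p = 0.0686 to 0.0836) and with median-of-ratios scaling (0.36, adjusted p = 0.110). The list did not pass (0.06 relative to other genes, adjusted p = 0.572). Endothelial (0.14, adjusted p = 0.866), atrial (0.01, adjusted p = 0.970), epicardial (0.13, adjusted p = 0.528), Schwann cell and neuron (0.14, adjusted p = 0.677) and adipocyte markers (0.00, adjusted p = 0.902) did not pass either, nor did calcium handling genes (-0.04, adjusted p = 0.510), the mitochondrially encoded list (-0.05, adjusted p = 0.970), atrophy genes (0.09, adjusted p = 0.511) and unfolded protein response genes (0.00, adjusted p = 0.958). Platelet markers (0.28, adjusted p = 0.113) passed without tumour 4 (adjusted p = 0.0428), skeletal muscle markers (-0.83, adjusted p = 0.0776) passed without tumour 1 or tumour 6 (-1.12 and -1.05), and immediate early genes (-0.29, adjusted p = 0.0911) passed without control 1, control 4 or control 5 (-0.42, -0.46 and -0.38). The direction of the immediate early list rests on control 2, without which it was 0.16 (adjusted p = 0.536). Single genes that were lower included Rtn4r, a receptor for inhibitors of axon growth, from 11.4 to 1.41 FPKM and Dbh, the noradrenaline-making enzyme gene, with a log2 fold change of -1.24. T and NK cell markers reached a highest group mean of 0.394 FPKM, for Trac.

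Whether Acta1 falls in a graded way as the acute phase score rises was left undecided across tumour-bearing hearts. Spearman's rho between them was -0.608 over the 12 tumour-bearing hearts (two-sided permutation p = 0.0413, and 0.112 adjusted over the 5 sets of hearts tested), and Pearson's r was -0.502 (permutation p = 0.0975). Within the 6 tumour hearts rho was -0.543 (exact p = 0.297) and r -0.701 (exact p = 0.117), and within the 6 tumour_swim hearts rho was 0.0857 (exact p = 0.919) and r 0.179 (exact p = 0.744), a positive value well within its spread. Without the 2 hearts with the farthest scores, tumour 6 and tumour_swim 1, r was -0.441 (permutation p = 0.199) and rho -0.503 (permutation p = 0.143), so the relation no longer reached 0.05 without both. Without tumour_swim 1 alone rho was -0.627 (permutation p = 0.0447) and r -0.599 (permutation p = 0.0552), so the pooled relation does not rest on that heart. The written rule asked for a negative rho in each group, which tumour_swim did not give. It counted a positive rho in 1 group against a graded response. With an exact p of 0.919 over 6 hearts, the positive rho of tumour_swim cannot decide against it. The 12 hearts also pool 2 groups whose mean scores and Acta1 levels lie apart in opposite directions, which alone can give a negative rho.

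Swimming may lower the acute phase response, but the test did not decide it. The acute phase score was 1.04 ± 0.31 in tumour_swim and 1.40 ± 0.29 in tumour hearts (SD, n = 6 each), a difference of -0.355 with an exact two-sided permutation p of 0.0649. Tumour_swim 1, which stood apart, had the lowest score, 0.512, against 0.915 to 1.35 in the other tumour_swim hearts. That library therefore carries part of the difference. Unlike the list values above, the score is not taken relative to other genes. Against control hearts the difference was 1.40 for tumour (exact p = 0.00216) and 1.04 for tumour_swim (exact p = 0.00433), and over the 3 comparisons the adjusted values were 0.00649 for both and 0.0649 for tumour_swim against tumour.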
